A study of Mus musculus with 12 samples.

How the data were processed

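Gene expression was measured by RNA sequencing in 12 samples of sorted mouse LSK cells. Per the labels, RNA was isolated with a PicoPure kit, libraries were made with TruSeq RNA and Nextera XT chemistry, and single-end reads of 75 nt were produced on a NextSeq instrument; all samples carry batch 1, and the mice were C57BL/6J; Sv/129. Per the submitters' processing notes, bcl2fastq 2.17, cutadapt 1.9.1, HISAT2, featureCounts 1.4.4, edgeR 3.28.0 and limma were used with the mm10 build; the notes do not give their roles. CPM stands for counts scaled to a common library size. The deposited values of each sample are raw counts per Ensembl gene for 39017 genes, equal in every cell to the deposited table of counts for the series. A second deposited table holds log2 values for 15759 genes, made by the authors as log2 of CPM after adding 0.5 to each count, with 1 scaled library size per sample, which could be recomputed from the counts to within 1e-09; it lists 1131 genes with no count. No column was left unmatched to a sample.

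Everything reported was computed from the raw counts. Totals ranged from 30453271 to 43790674 counts per library, so that 3 counts in the shallowest library, the floor used for genes with no count in a group, are 0.099 CPM. Of the 39017 genes 15330 had no count in any library, and the 37 mitochondrial genes had 0 counts in every library, which made the fixed list of 13 mitochondrially encoded genes void. Symbols were taken from the GENCODE M21 annotation and matched 37607 genes; 212 of the tested genes had none. After edgeR's filterByExpr by group 16024 genes were tested, which hold at least 99.92% of the counts of each library. Counts were scaled by TMM, and CPM refers to the scaled library size. A quasi-likelihood model with 1 mean per group and robust dispersion was fitted over all 12 libraries in edgeR 4.0.16 (R 4.3.3; common biological coefficient of variation 0.3), and each contrast was tested by the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. SE was taken as the log2 fold change divided by the square root of F. The p-values measure only the spread between these samples, since the labels do not say whether replicates are separate mice.

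Groups were taken from the labels of N1IC and Tcf7. The 4 pairwise contrasts and the interaction were defined before the data were examined, as were 25 gene lists (497 members, 468 distinct genes), of which 23 entered adjusted tests: Notch target, T cell receptor, early T lineage, Wnt target, stem cell, lymphoid-primed, granulocyte and monocyte, erythroid, megakaryocyte, B lineage, NK and innate lymphoid, dendritic cell and MHC class II, mast cell and basophil, stromal and endothelial, plasma cell, cell cycle, quiescence, Myc and ribosome biogenesis, interferon-stimulated, immediate-early, p53 target, T-ALL oncogene and chromatin regulator genes. Some genes stand in several lists. Each list was tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation; fry was run beside it. The genes named are Tcf7 and Notch1, then per contrast the 10 higher and 10 lower genes with the largest absolute log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries (5 and 5 for the interaction, without the rule on overlap). Predicted genes named by number, Rik clones, pseudogenes ending in Ps, segments of antigen receptors and sex-linked genes were left out of this choice. Up to 4 members per list and contrast with the smallest p follow, and Hes1, Dtx1, Nrarp, Notch3, Ptcra, Il2ra, Gata3, Bcl11b, Cd3e, Lef1, Myc and Axin2. Some members outside this choice, of lists with 5 or fewer genes in a direction, were named after their values were seen, and so were the examples of overlaps. A gene of this choice is not reported here. Genes of this choice whose call was lost without 1 library were mostly left unnamed, as were an antisense transcript and lower-case pseudogenes.

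Alternatives chosen before the data were examined were RLE size factors, no filter on low counts, a filter of at least 1 CPM in at least 3 samples, DESeq2 1.42.0, limma-voom, a fit of only the groups of a contrast, a replicate block, a covariate for library sheets inferred from numbers that recur in the sample titles, the deposited series table, leaving out Y-linked genes and Xist, and leaving out each library in turn. A covariate for sex and 2 further pairwise contrasts were chosen after seeing the data, as were the main effects of labelled N1IC and labelled Tcf7 loss used in the closing section. Ratios against a group with 1 to 3 counts carry an exact binomial 95% interval, and a group with no count was set to 3 counts in each library. The floor was taken from the mean library at first and changed to the shallowest one afterwards. Overlaps of gene sets were set beside those of independent lists and beside simulated unchanged groups that share the control libraries.

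The procedure was tested on simulated data with the same depths and spread. Of genes changed 2-fold, 52, 35, 46 and 45% were recovered in the 4 pairwise contrasts and 33% in the interaction, and of genes changed 4-fold 75, 66, 81, 78 and 64%; in the 2 added contrasts 49 and 57% and 69 and 78% were recovered. Between 2.8 and 5.8% of calls were false, and a planted list was found in each of 7 contrasts with 0 unchanged lists called by camera. Genes were simulated independently of each other, so this check does not cover lists whose genes move together. Raw reads were not analysed here.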

Results

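RNA was sequenced from sorted Lin- Sca1+ cKit+ (LSK) cells from mouse bone marrow, the compartment that holds haematopoietic stem cells and multipotent progenitors. Per the labels, the mice carried an inducible Notch1 intracellular domain (N1IC, the constitutively active form of Notch1) at the R26 locus, a lox-flanked Tcf7 gene, both, or neither, and poly(I:C) was given at 2 ug/g to induce Mx1Cre. The 12 libraries fell into 4 groups of 3, labelled NOTCHWT_TCFWT (wild type), NICD_TCFWT (N1IC), NICD_TCFKO (N1IC with Tcf7 deleted) and NOTCHWT_TCFKO (Tcf7 deleted). Cells of both NICD groups were in addition gated as CD45.2+ eGFP+, so this gate and the N1IC label coincide in every library. Total counts were 35138712, 30453271 and 43790674 in NOTCHWT_TCFWT, 35947505, 38323866 and 36259054 in NICD_TCFWT, 40094252, 42984907 and 39927224 in NICD_TCFKO, and 37488803, 38243891 and 40357607 in NOTCHWT_TCFKO. Expression is given as normalised read counts (CPM), mean ± SD of 3 libraries, and changes as log2 fold change ± SE.

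The 2 genes that the labels name did not follow the labels in every pair of groups. Tcf7, which encodes the T cell transcription factor TCF-1 (ENSMUSG00000000782, mm10 chromosome 11, 52252371 to 52283014), was at 603 ± 300 CPM in the libraries labelled NICD_TCFKO, where it is stated to be deleted. In those labelled NOTCHWT_TCFWT it was at 14.8 ± 4.54 CPM. It was at 5.5 ± 1.11 CPM in the libraries labelled NICD_TCFWT and at 1.28 ± 1.31 CPM in those labelled NOTCHWT_TCFKO. Notch1, the receptor gene (ENSMUSG00000026923, mm10 chromosome 2, 26457903 to 26516663), was at 571 ± 44.4, 180 ± 19.9, 774 ± 160 and 149 ± 46.7 CPM in the libraries labelled NOTCHWT_TCFWT, NICD_TCFWT, NICD_TCFKO and NOTCHWT_TCFKO. Dtx1, a gene induced by Notch signalling, split the libraries in the same way. It was at 85.4 ± 5.67 and 121 ± 51.3 CPM in those labelled NOTCHWT_TCFWT and NICD_TCFKO, against 0.124 ± 0.0602 and 0.208 ± 0.189 CPM in those labelled NICD_TCFWT and NOTCHWT_TCFKO. The counts are per gene and the labels do not state which exons the lox sites flank, so transcripts of remaining exons would still be counted for Tcf7. Transcripts of N1IC, a part of Notch1, could likewise be counted for Notch1. The sample titles carry a second name for each library, in which those labelled NICD_TCFWT are called RNIC with CTRL, those labelled NICD_TCFKO RNIC with Tg, those labelled NOTCHWT_TCFKO Tcf7 with Tg, and those labelled NOTCHWT_TCFWT RAD. RNIC thus stands in the names of both groups labelled N1IC and Tg in those of both groups labelled Tcf7-deleted. CTRL stands in that of a group labelled Tcf7 intact. Read in this way, the names follow the labels. CTRL and Tg could also stand for libraries without and with a transgene, which would go against the label N1IC of those named CTRL. The meaning of these names was not settled here. Notch1 went against the N1IC label between NICD_TCFWT and NOTCHWT_TCFWT, but with it between NICD_TCFKO and NOTCHWT_TCFKO. Tcf7 went against its label between NICD_TCFKO and NICD_TCFWT, but with it between NOTCHWT_TCFKO and NOTCHWT_TCFWT. Since both genes go against the labels in part, groups are called by their labels throughout. Every direction given is one between libraries so labelled.

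**Figure D1:**
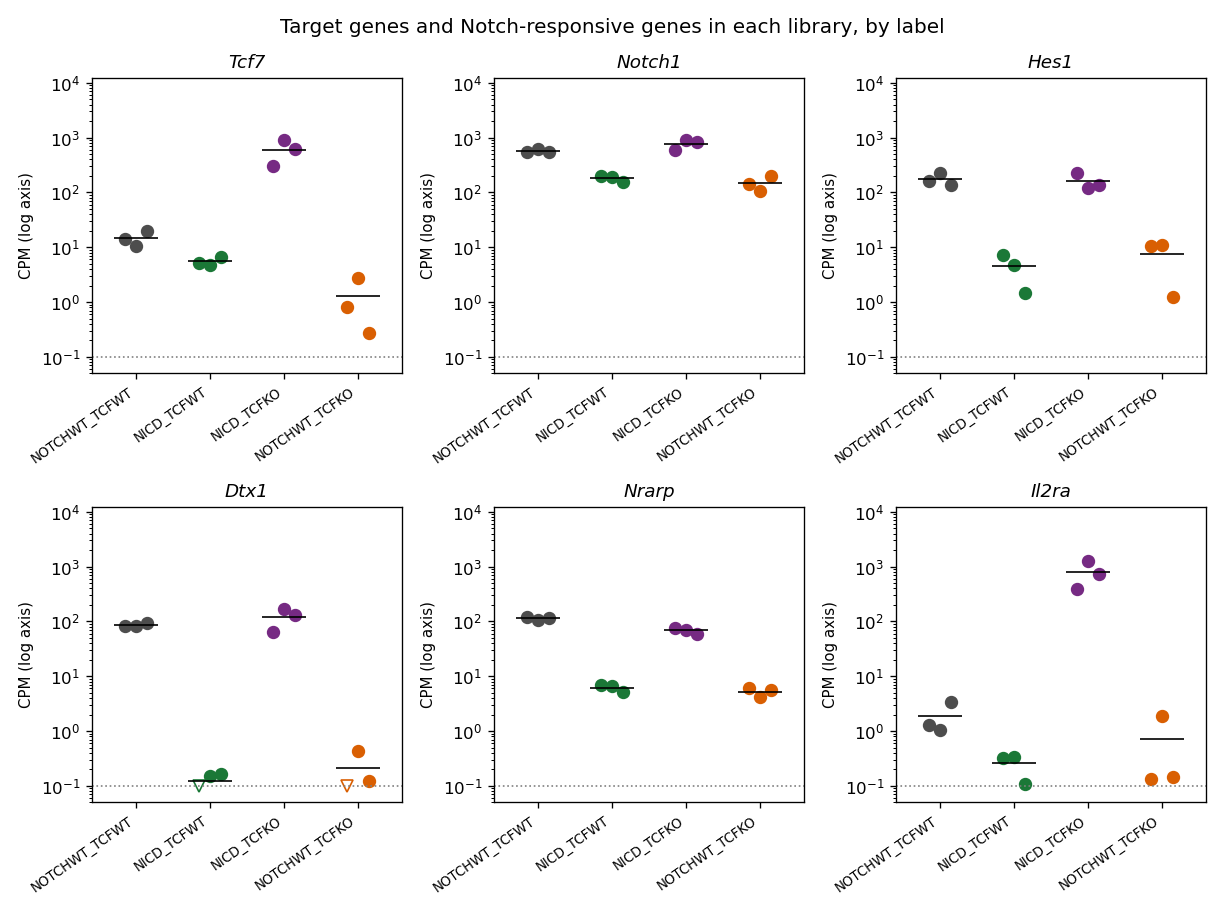
CPM of Tcf7, Notch1, Hes1, Dtx1, Nrarp and Il2ra (log axis) in each of the 12 libraries, by labelled group; points are libraries, horizontal lines group means, the dotted line marks 3 counts in the shallowest library (0.099 CPM) and open triangles are libraries below it. Dtx1 is at a mean of 85.4 and 121 CPM in the libraries labelled NOTCHWT_TCFWT and NICD_TCFKO and at 0.124 and 0.208 CPM in the other two groups.

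The first 3 principal components of log2 CPM held 36, 19.7 and 15.1% of the variance. On the first, libraries labelled NOTCHWT_TCFWT scored from -77.74 to -71.8 and those labelled NOTCHWT_TCFKO from 62.37 to 107.4, with the libraries labelled NICD_TCFKO (-51.34 to -11.22) and NICD_TCFWT (15.69 to 47.03) between them. Replicates of a group correlated at 0.938 to 0.982 over genes (Pearson's r of log2 CPM, across genes, which are not independent replicates). Xist and Y-linked counts showed that the sexes were not balanced: all 3 libraries labelled NOTCHWT_TCFWT were Xist-high, the other groups held both kinds, and the library NOTCHWT_TCFKO 1 held Xist at 2160 CPM together with 154 CPM of Y-linked transcripts. Of the 5 fixed sex-linked genes, which were kept out of the adjusted tests of lists, the lowest adjusted p in the 4 pairwise comparisons and the interaction was that of Eif2s3y between the libraries labelled NICD_TCFWT and NOTCHWT_TCFWT (adjusted p = 0.117).

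**Figure D2:**
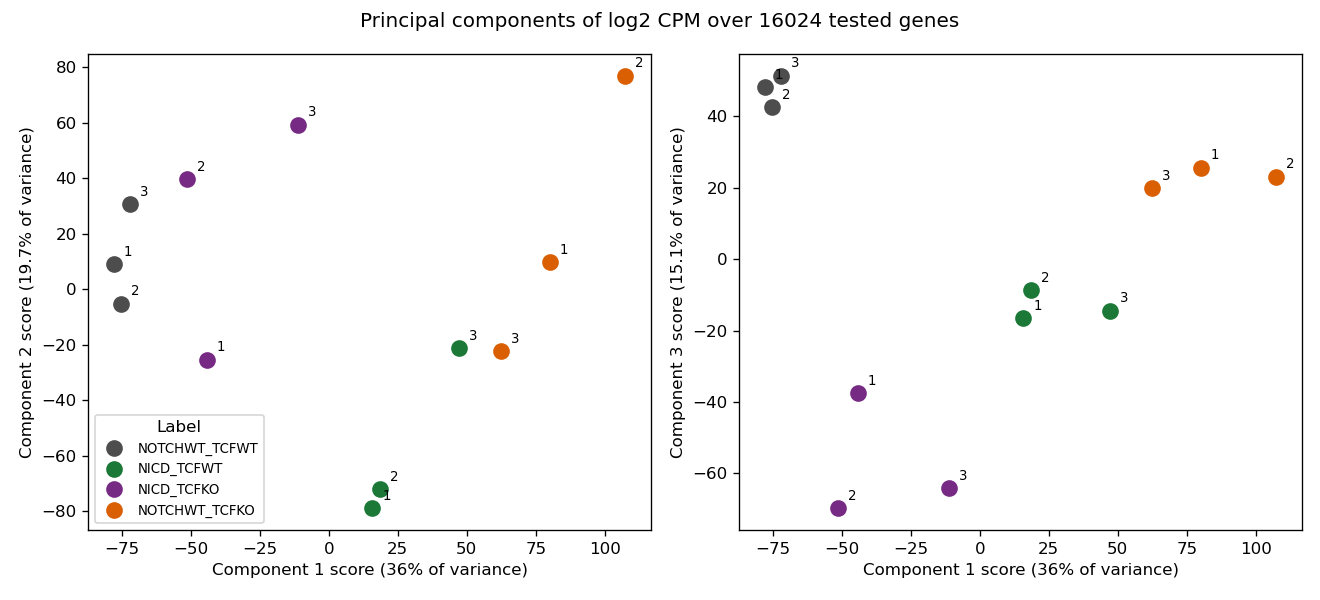
Principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with the percent of variance of each on its axis; points are the 12 libraries, coloured by labelled group and numbered by replicate. Component 1 (36%) sets the libraries labelled NOTCHWT_TCFWT (lowest -77.74) apart from those labelled NOTCHWT_TCFKO (highest 107.4).

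What N1IC changes in cells that keep Tcf7 is asked by the libraries labelled NICD_TCFWT against those labelled NOTCHWT_TCFWT. In the libraries labelled NICD_TCFWT 8 of 17 Notch target genes and 10 of 26 T cell receptor genes were lower (4 and 3 higher), and 12 of 25 granulocyte and monocyte genes and 11 of 30 stem cell genes higher. With an estimated correlation Notch target genes passed camera (adjusted p = 0.00783), while the other lists did not, with adjusted p = 0.569, 0.53 and 0.777 in this order. The direction rests on labels that Tcf7 and Notch1 go against. Hes1, a transcriptional repressor induced by Notch, fell from 177 ± 47.8 to 4.54 ± 2.94 CPM, and Nrarp, a feedback inhibitor of Notch signalling, from 114 ± 6.32 to 6.15 ± 0.865 CPM. Gzmb, the cytotoxic protease granzyme B, fell from 1010 ± 371 to 3.95 ± 0.32 CPM, and Trbc2, a constant region of the T cell receptor beta chain, from 136 ± 13.9 to 0.411 ± 0.133 CPM. Cebpa, the transcription factor that directs granulocyte and monocyte fate, rose from 0.0636 to 50.8 ± 28.3 CPM, and Mpo, the myeloperoxidase of their granules, from 23.5 ± 10.3 to 2700 ± 1770 CPM. Both were highest in NICD_TCFWT 3, with Cebpa at 82.7 against 28.5 and 41.3 CPM in NICD_TCFWT 1 and 2. Mpo was at 4680 against 1250 and 2160 CPM in the same order.

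Among the genes with the largest changes, the lower ones also held the Notch target Hey1 (80 ± 25.3 to 0.346 ± 0.231 CPM) and the tight junction gene Cldn10 (27.4 ± 4.24 to 0.212 ± 0.186 CPM). Adamtsl1 was 605-fold lower, with a counting interval of 108 to 24000. Higher were Tpsb2, a tryptase of mast cells, with 1 count in all libraries labelled NOTCHWT_TCFWT and 26 ± 6.44 CPM in those labelled NICD_TCFWT (2810-fold, counting interval 503 to 111000), and the imprinted non-coding RNA Meg3 (753-fold, 135 to 29800). Also higher were the chemokine Ccl9 (0.843 ± 0.429 to 239 ± 104 CPM), the transporter Slc16a11 (0.077 ± 0.052 to 36.7 ± 16.1 CPM) and Zfp990 (0.368 ± 0.233 to 98.3 ± 6.04 CPM). Such intervals, and the bounds from 3 counts per library given further on, cover counting error only, and fitted log2 changes of genes with 0 to 3 counts in a group depend on the prior count. For each gene named by the size of its change, and each list member named in the 4 pairwise comparisons, the 3 libraries of one group lay outside the range of the 3 of the other unless stated.

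In the gene lists, counts in parentheses are adjusted over the list alone. Of 17 Notch target genes 8 fell and 4 rose (10 and 5); Dtx1 changed by -9.39 ± 0.57, Nrarp by -4.21 ± 0.16 and Notch3 by -3.51 ± 0.40, while Myc was among the 4 that rose (0.57 ± 0.11). The list passed camera as lower (adjusted p = 3.44e-07, and adjusted p = 0.00783 with an estimated correlation). Of 26 T cell receptor genes 10 fell and 3 rose (10 and 3). The kinase Fyn changed by -1.13 ± 0.14 and the co-receptor Cd4 by 1.83 ± 0.26 (list by camera lower, adjusted p = 0.00745, but adjusted p = 0.569 with an estimated correlation). Granulocyte and monocyte genes moved one way: 12 of 25 rose (15). Csf3r, the G-CSF receptor, changed by 2.44 ± 0.39 and the chemokine receptor Ccr2 by 5.40 ± 0.83. None of the list fell in edgeR, DESeq2 or voom or at an unadjusted p under 0.05 (0 genes each). Camera gave this list as higher with adjusted p = 5.81e-07, and adjusted p = 0.53 with an estimated correlation. Of 30 haematopoietic stem cell genes 11 rose and 2 fell (12 and 5). The cell cycle inhibitor Cdkn1c changed by 3.59 ± 0.45, the growth suppressor Ndn by 3.62 ± 0.64 and Mycn by -2.34 ± 0.22 (list adjusted p = 0.0154, and adjusted p = 0.777 with an estimated correlation). Lymphoid-primed progenitor genes rose in 8 and fell in 3 of 18 (8 and 3). Flt3, the cytokine receptor of these progenitors, changed by 3.32 ± 0.32 and Notch1 by -1.66 ± 0.22 (list adjusted p = 0.00884, and adjusted p = 0.53 with an estimated correlation). Megakaryocyte genes rose in 7 and fell in 1 of 18 (9 and 2), with platelet factor Pf4 at 5.03 ± 0.72 and Gp9 at 1.85 ± 0.39 (adjusted p = 0.00884, and adjusted p = 0.625 with an estimated correlation). Interferon-stimulated genes fell in 9 and rose in 4 of 29 (10 and 4), with Isg15 at -1.63 ± 0.30 (adjusted p = 0.00884, and adjusted p = 0.667 with an estimated correlation). T-ALL oncogenes rose in 8 and fell in 2 of 18 (8 and 2), with the survival gene Bcl2 at 2.57 ± 0.19 and Lmo1 at 1.54 ± 0.22 (adjusted p = 0.0177, and adjusted p = 0.502 with an estimated correlation).

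Chromatin regulators fell in 6 of 30 (6), the co-repressor Tle1 by -1.74 ± 0.18 and Arid1a by -0.34 ± 0.08. Of this list 0 rose in edgeR, DESeq2 or voom or at an unadjusted p under 0.05 (camera lower, adjusted p = 0.00882, and adjusted p = 0.53 with an estimated correlation). Stromal and endothelial genes rose in 3 and fell in 1 of 11 (3 and 1), with the sialomucin Emcn at 4.47 ± 0.43 (adjusted p = 0.0355, and adjusted p = 0.569 with an estimated correlation). The other lists did not pass camera. Among these, early T lineage regulators fell in 4 and rose in 2 of 25 (5 and 2), with Cd7 at -5.52 ± 0.74 and Dntt, the terminal transferase of lymphoid progenitors, at 5.02 ± 0.74. Dendritic cell and MHC class II genes fell in 6 and rose in 1 of 16 (6 and 1), with H2-Ab1 at -2.06 ± 0.39. NK and innate lymphoid genes fell in 4 and rose in 3 of 18 (4 and 3). Gzmb changed by -7.99 ± 0.58 and the transcription factor Zbtb16 by 5.35 ± 0.47. Wnt target genes rose in 4 and fell in 1 of 13 (6 and 1), B lineage genes rose in 3 and fell in 2 of 19 (4 and 2) and mast cell genes rose in 3 and fell in 2 of 12 (3 and 3). Quiescence genes rose in 2 and fell in 3 of 10 (2 and 3) and p53 targets rose in 1 and fell in 3 of 16 (1 and 7). In plasma cell genes 1 of 11 rose (1) and in Myc and ribosome biogenesis genes 1 of 26 (0). No erythroid gene of 20 and no immediate-early gene of 18 passed in edgeR, DESeq2 or voom, or at an unadjusted p under 0.05 (0 each). Of 30 cell cycle genes 0 passed in any of these tools, with 1 higher and 1 lower at an unadjusted p under 0.05.

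In all, 1701 genes were higher and 1562 lower of 16024 tested (20.4%), of which 989 and 612 changed at least 2-fold; with the replicate block the counts were 1427 and 1323. Leaving out 1 library moved the higher count by over 1.5 times for NOTCHWT_TCFWT 1 (1103) and 3 (1073), and the lower count for NOTCHWT_TCFWT 1 (1005), NICD_TCFWT 1 (873) and 2 (1002). Tcf7 itself did not pass (-1.43 ± 0.59, adjusted p = 0.121), and Notch1 was lower in the libraries labelled NICD_TCFWT (-1.66 ± 0.22, adjusted p = 0.000707).

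**Figure D3:**
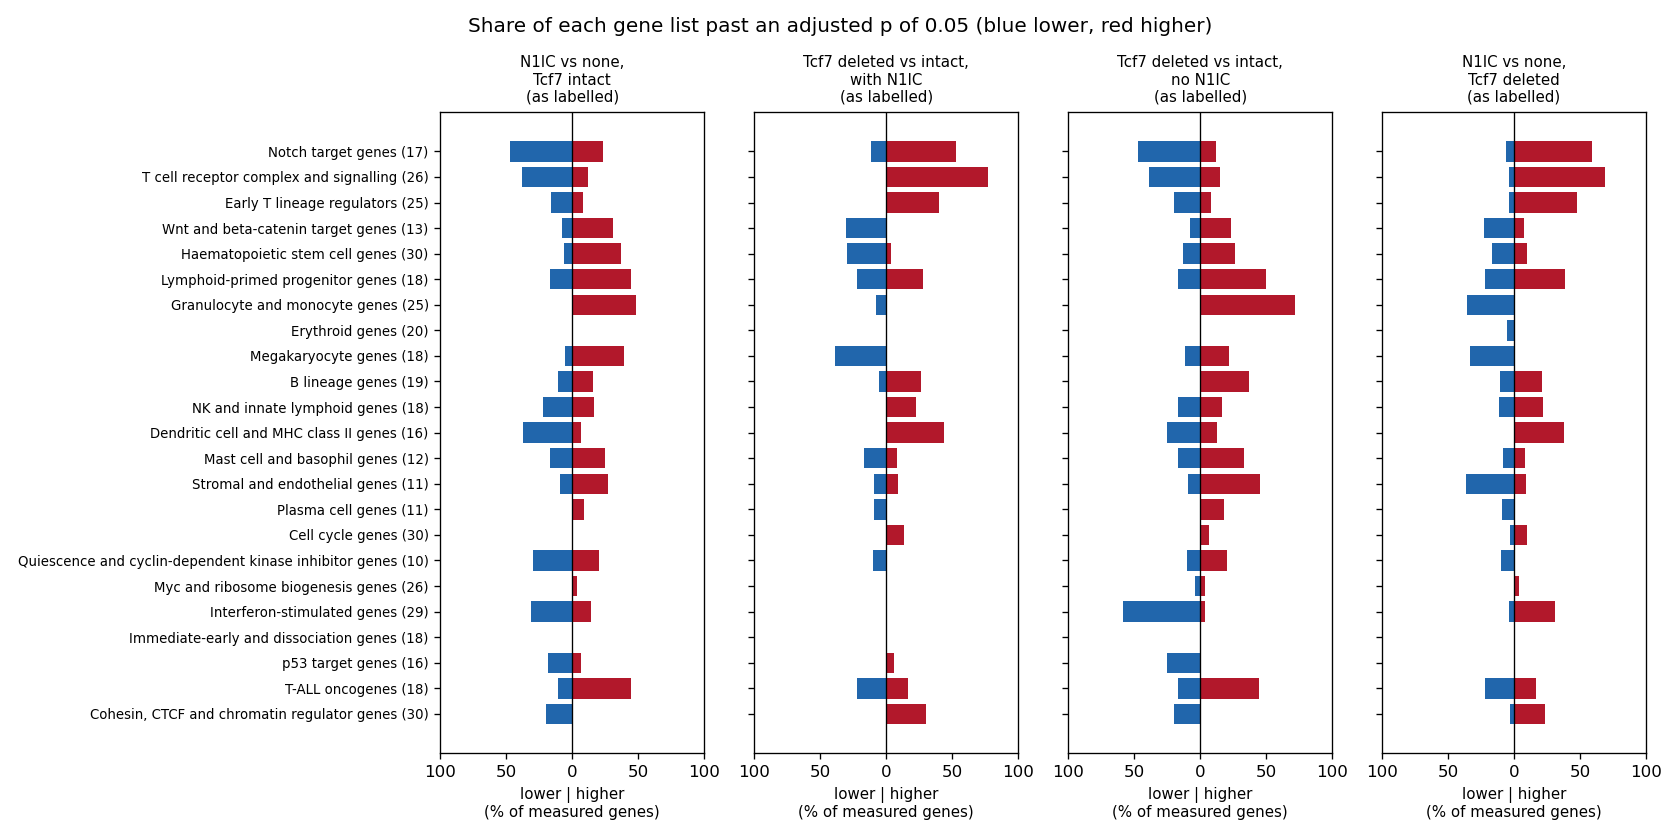
Percent of the measured genes of each fixed list that were called higher (red, to the right) or lower (blue, to the left) in the 4 pairwise comparisons of labelled groups, edgeR adjusted p under 0.05. Of 17 Notch target genes 8 are lower and 4 higher in NICD_TCFWT against NOTCHWT_TCFWT, 8 lower and 2 higher in NOTCHWT_TCFKO against NOTCHWT_TCFWT, and 9 and 10 higher in NICD_TCFKO against NICD_TCFWT and against NOTCHWT_TCFKO.

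Deletion of Tcf7 in cells with N1IC is asked by the libraries labelled NICD_TCFKO against those labelled NICD_TCFWT. In the libraries labelled NICD_TCFKO 20 of 26 T cell receptor genes and 10 of 25 early T lineage regulators were higher, calls of lists that were lost with an estimated correlation (adjusted p = 0.0731 and adjusted p = 0.103). Tcf7 was higher too (6.78 ± 0.71, adjusted p = 0.000681), a direction opposite to the deletion that the label states. Il2ra, the interleukin 2 receptor alpha chain of early thymocytes, rose from 0.256 ± 0.128 to 802 ± 438 CPM. Ptcra, the pre-T cell receptor alpha chain, had no count in the libraries labelled NICD_TCFWT and 8.52 ± 6.57 CPM in those labelled NICD_TCFKO, at least 86-fold higher against the floor of 3 counts per library. Bcl11b, which commits progenitors to the T lineage, rose from 0.489 to 66.3 ± 42.2 CPM, and Gata3, a regulator of early T cells, from 11.4 ± 1.31 to 51.2 ± 18 CPM.

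Further genes with large increases were Prss2 (0.0447 to 41.8 ± 21.2 CPM), Tcrg-C2, a constant region of the T cell receptor gamma chain (0.232 ± 0.0728 to 118 ± 74.4 CPM), and Trbc2 (8.72 ± 0.86). Dtx1 rose by 9.89 ± 0.57, Hes1 by 5.12 ± 0.83, Notch3 by 4.50 ± 0.42 and Notch1 by 2.11 ± 0.22. Cd3g rose from 0 counts to 66.2 ± 45 CPM, at least 667-fold, but its call was lost without NICD_TCFKO 2 (adjusted p = 0.0527), with only these groups fitted (adjusted p = 0.0512) and in voom (adjusted p = 0.096). On the lower side stood Tpsb2, from 26 ± 6.44 CPM to 0 counts (at least 262-fold lower), Slc16a11 (36.7 ± 16.1 to 0.473 ± 0.346 CPM) and Pf4 (22.8 ± 8.89 to 1.33 ± 1.17 CPM). Also lower were the potassium channel subunit Kcng1 (22.8 ± 6.45 to 1.42 ± 0.657 CPM), Cebpa (-3.84 ± 0.65) and the granule protein Chga (-3.81 ± 0.73).

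In this comparison 20 of 26 T cell receptor genes rose (22 adjusted over the list alone) and 0 fell in edgeR, DESeq2 or voom or at an unadjusted p under 0.05. Cd5 rose by 4.10 ± 0.44 and the adaptor Lcp2 by 0.96 ± 0.09 (list by camera, adjusted p = 1.67e-22, and adjusted p = 0.0731 with an estimated correlation). The library NICD_TCFKO 1, the only one of its group with Y-linked transcripts (355 CPM) and with low Xist (0.5 CPM), held less of some T cell genes than NICD_TCFKO 2 and 3. It had Cd3e at 3.88 against 26 and 28.6 CPM, Cd3g at 14.3 against 89.8 and 94.6 CPM and Bcl11b at 17.8 against 86.3 and 94.7 CPM. Of 17 Notch target genes 9 rose and 2 fell (10 and 4 adjusted over the list alone), Myc (-0.60 ± 0.11) being lower (camera higher, adjusted p = 5.74e-13, and adjusted p = 0.00146 with an estimated correlation). In the counts that follow, values in parentheses are again adjusted over the list alone. Early T lineage regulators rose in 10 and fell in 0 of 25 (12 and 2). Ets1 changed by 1.85 ± 0.26 and Ikzf2 by 0.75 ± 0.08. At an unadjusted p under 0.05 edgeR gave 2 of the list lower, DESeq2 1 and voom 0 (list adjusted p = 4.57e-08, and adjusted p = 0.103 with an estimated correlation). Dendritic cell and MHC class II genes rose in 7 of 16 (9), with the integrin Itgax at 2.70 ± 0.33, and 0 fell by any of these counts (adjusted p = 3.73e-08, and adjusted p = 0.205 with an estimated correlation). Chromatin regulators rose in 9 of 30 (11), the co-repressor Tle3 by 0.91 ± 0.15 and the Polycomb methyltransferase Ezh2 by 0.51 ± 0.09. Of these regulators 0 fell by any of these counts (list adjusted p = 3.84e-05, and adjusted p = 0.205 with an estimated correlation). Cell cycle genes rose in 4 of 30 (6) with 0 lower by any of these counts, by small amounts such as 0.46 ± 0.10 for Uhrf1, whose call was lost without NICD_TCFWT 3 (adjusted p = 0.0603). The list's camera adjusted p = 0.000128 became adjusted p = 0.645 with an estimated correlation.

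Megakaryocyte genes fell in 7 of 18 (12) and rose in 0 by any of these counts. Gp9 changed by -2.10 ± 0.39 and Treml1 by -2.24 ± 0.43 (list adjusted p = 1.3e-08, and adjusted p = 0.205 with an estimated correlation). Stem cell genes fell in 9 and rose in 1 of 30 (13 and 1). Cdkn1c changed by -2.21 ± 0.42, Cd34 by -0.97 ± 0.19 and Mycn by 1.92 ± 0.22 (list adjusted p = 1.49e-06, and adjusted p = 0.426 with an estimated correlation). Granulocyte and monocyte genes fell in 2 of 25 (4), Cebpa and Csf3r (275 ± 43.8 to 68.9 ± 24.9 CPM), and rose in 0 by any of these counts (adjusted p = 0.0413, and adjusted p = 0.645 with an estimated correlation). The other lists did not pass camera: lymphoid-primed progenitor genes rose in 5 and fell in 4 of 18 (9 and 4), with Il7r at 3.76 ± 0.53 and Flt3 at -2.20 ± 0.30. B lineage genes rose in 5 and fell in 1 of 19 (6 and 1) and T-ALL oncogenes rose in 3 and fell in 4 of 18 (3 and 5). NK and innate lymphoid genes rose in 4 and fell in 0 of 18 (4 and 0). Gzmb changed by 5.62 ± 0.53, and 2 of the list were lower at an unadjusted p under 0.05, 1 in DESeq2 and 0 in voom. Wnt target genes fell in 4 and rose in 0 of 13 (5 and 2), with 2 higher at an unadjusted p under 0.05, 2 in DESeq2 and 0 in voom. Axin2, the feedback gene of that pathway, was at 1.97 ± 0.314 and 4.64 ± 1.6 CPM and did not pass. Interferon-stimulated genes passed in 0 of 29 in edgeR, with 3 higher and 2 lower at an unadjusted p under 0.05, 3 and 1 in DESeq2 and 0 in voom.

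The comparison gave 1161 genes higher and 825 lower of 16024 (12.4%), 484 and 339 of them at least 2-fold, and 902 and 649 with the replicate block. Both counts moved by over 1.5 times without NICD_TCFWT 1 (564 and 368), 2 (602 and 332) or 3 (652 and 412), or without NICD_TCFKO 2 (582 and 335) or 3 (730 and 408), and DESeq2 called 1468 lower.

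Loss of Tcf7 without the transgene is asked by the libraries labelled NOTCHWT_TCFKO against those labelled NOTCHWT_TCFWT. Tcf7 was lower in the former (-3.55 ± 0.68, adjusted p = 0.00603), the direction that the label states, while Notch1, which no label sets apart here, was lower as well, as were 8 of 17 Notch target genes (2 were higher). Gzmb fell from 1010 ± 371 to 1.86 ± 1.13 CPM, Dtx1 by -8.67 ± 0.54 and Notch1 by -1.94 ± 0.22. Of 25 granulocyte and monocyte genes 18 rose, a call of the list that was lost with an estimated correlation (adjusted p = 0.407). Cebpa rose from 0.0636 to 61.1 ± 23.4 CPM and Mpo from 23.5 ± 10.3 to 3790 ± 2470 CPM. Both were lowest in NOTCHWT_TCFKO 3, with Cebpa at 34.7 against 69.7 and 79 CPM in NOTCHWT_TCFKO 1 and 2. Mpo was at 949 against 5080 and 5340 CPM in the same order. Some genes of tissue macrophages were high in all 3 libraries labelled NOTCHWT_TCFKO. Fcna, a ficolin, was at 41.1 ± 7.49 CPM in them (4420-fold, counting interval 792 to 174000) and Cd5l at 26.9 ± 4.62 CPM (2880-fold, 517 to 114000). The adhesion receptor Vcam1 was at 149 ± 35.5 against 1.31 ± 0.204 CPM and the complement gene C1qa at 35.4 ± 4.73 against 0.231 ± 0.101 CPM.

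Several genes had counts in every other group and none in the libraries labelled NOTCHWT_TCFKO. Itln1, an intestinal lectin, was at 12.7 ± 0.777 CPM in the libraries labelled NOTCHWT_TCFWT (at least 128-fold lower in those labelled NOTCHWT_TCFKO). Klk1b22, a kallikrein, was there at 10.7 ± 2.67 CPM (at least 108-fold) and Ccnb1ip1 at 5.1 ± 5.42 CPM (at least 51.4-fold). The absence of these genes from a whole group could also mark a strain segment of the mixed background, which the test in the closing section leaves open. Also lower were Trbc2 (136 ± 13.9 to 0.554 ± 0.808 CPM) and the glutamate receptor Grm4 (28.6 ± 7.4 to 0.176 ± 0.145 CPM). Elane, the neutrophil elastase, rose from 0.434 ± 0.206 to 530 ± 403 CPM and the mast cell protease Prss34 from 0.115 to 75.3 ± 96.5 CPM; neither passed in limma-voom (adjusted p = 0.184 and adjusted p = 0.198).

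Of 25 granulocyte and monocyte genes 18 rose (23 adjusted over the list alone) and 0 fell in edgeR, DESeq2 or voom or at an unadjusted p under 0.05, in libraries where Fcna and C1qa were also high. Csf3r rose by 2.28 ± 0.39 and Cd68, a macrophage protein, by 1.41 ± 0.19 (list by camera, adjusted p = 5.07e-11, and adjusted p = 0.407 with an estimated correlation). In the following counts, values in parentheses are adjusted over the list alone. Notch target genes fell in 8 and rose in 2 of 17 (8 and 2). Nrarp fell from 114 ± 6.32 to 5.24 ± 0.942 CPM, Hes1 changed by -4.53 ± 0.80 and Notch3 by -4.80 ± 0.43 (list adjusted p = 1.94e-08, and adjusted p = 0.00854 with an estimated correlation). T cell receptor genes fell in 10 and rose in 4 of 26 (10 and 4). Fyn changed by -1.49 ± 0.14 and Cd4 by 2.71 ± 0.27 (list adjusted p = 0.00184, and adjusted p = 0.567 with an estimated correlation). The library NOTCHWT_TCFKO 2 stood apart in this list, with 30 counts of Trac, 65 of Cd3e and 71 of Cd3g, against 0 or 1 count of each in NOTCHWT_TCFKO 1 and 3. Interferon-stimulated genes fell in 17 and rose in 1 of 29 (17 and 2). Isg15 changed by -1.88 ± 0.30 and the RNA sensor Ifih1 by -0.83 ± 0.13. The 1 that rose was Rsad2 (1.77 ± 0.26; list adjusted p = 1.26e-06, and adjusted p = 0.407 with an estimated correlation). Stromal and endothelial genes rose in 5 and fell in 1 of 11 (7 and 1), with Vcam1 and Emcn (4.78 ± 0.43) among the higher (adjusted p = 0.000249, and adjusted p = 0.407 with an estimated correlation). Lymphoid-primed progenitor genes rose in 9 and fell in 3 of 18 (9 and 3). Flt3 changed by 3.02 ± 0.31 and Dntt by 5.39 ± 0.76 (list adjusted p = 0.00184, and adjusted p = 0.407 with an estimated correlation). B lineage genes rose in 7 of 19 (10, with 1 lower), with Blnk, a B cell adaptor, at 7.94 ± 0.77 and Il7r at 4.70 ± 0.59. Of these genes 0 fell in edgeR, with 1 lower at an unadjusted p under 0.05, 1 in DESeq2 and 1 in voom (list adjusted p = 0.00293, and adjusted p = 0.567 with an estimated correlation). Plasma cell genes rose in 2 of 11 (3), Sdc1 by 3.85 ± 0.52 (adjusted p = 0.0259, and adjusted p = 0.745 with an estimated correlation).

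The other lists did not pass camera. Stem cell genes rose in 8 and fell in 4 of 30 (12 and 5), with Cdkn1c at 3.62 ± 0.45 and Ly6a, the Sca1 antigen, at -1.71 ± 0.25. T-ALL oncogenes rose in 8 and fell in 3 of 18 (8 and 3), with Bcl2 at 2.40 ± 0.18 and Mycn at -2.52 ± 0.22, and early T lineage regulators fell in 5 and rose in 2 of 25 (5 and 2). Chromatin regulators fell in 6 of 30 (6), with Arid1a at -0.57 ± 0.08 and the methyltransferase Dnmt3a at -0.62 ± 0.11; 0 rose in edgeR, with 2 higher at an unadjusted p under 0.05, 2 in DESeq2 and 0 in voom. Mast cell genes rose in 4 and fell in 2 of 12 (4 and 3), with Il4 at -4.24 ± 0.69 and Cpa3, the mast cell carboxypeptidase, at -2.30 ± 0.26. Targets of p53 fell in 4 of 16 (6), with 0 higher in edgeR, DESeq2 or voom or at an unadjusted p under 0.05. Of 20 erythroid genes 0 passed in edgeR, DESeq2 or voom, with 4 higher at an unadjusted p under 0.05.

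Here 1738 genes were higher and 1675 lower of 16024 (21.3%), 1067 and 692 at least 2-fold, and 1479 and 1425 with the replicate block. The higher count moved by over 1.5 times without NOTCHWT_TCFWT 1 (1118), and the lower count without NOTCHWT_TCFWT 1 (1083) or NOTCHWT_TCFKO 1 (1008).

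**Figure D4:**
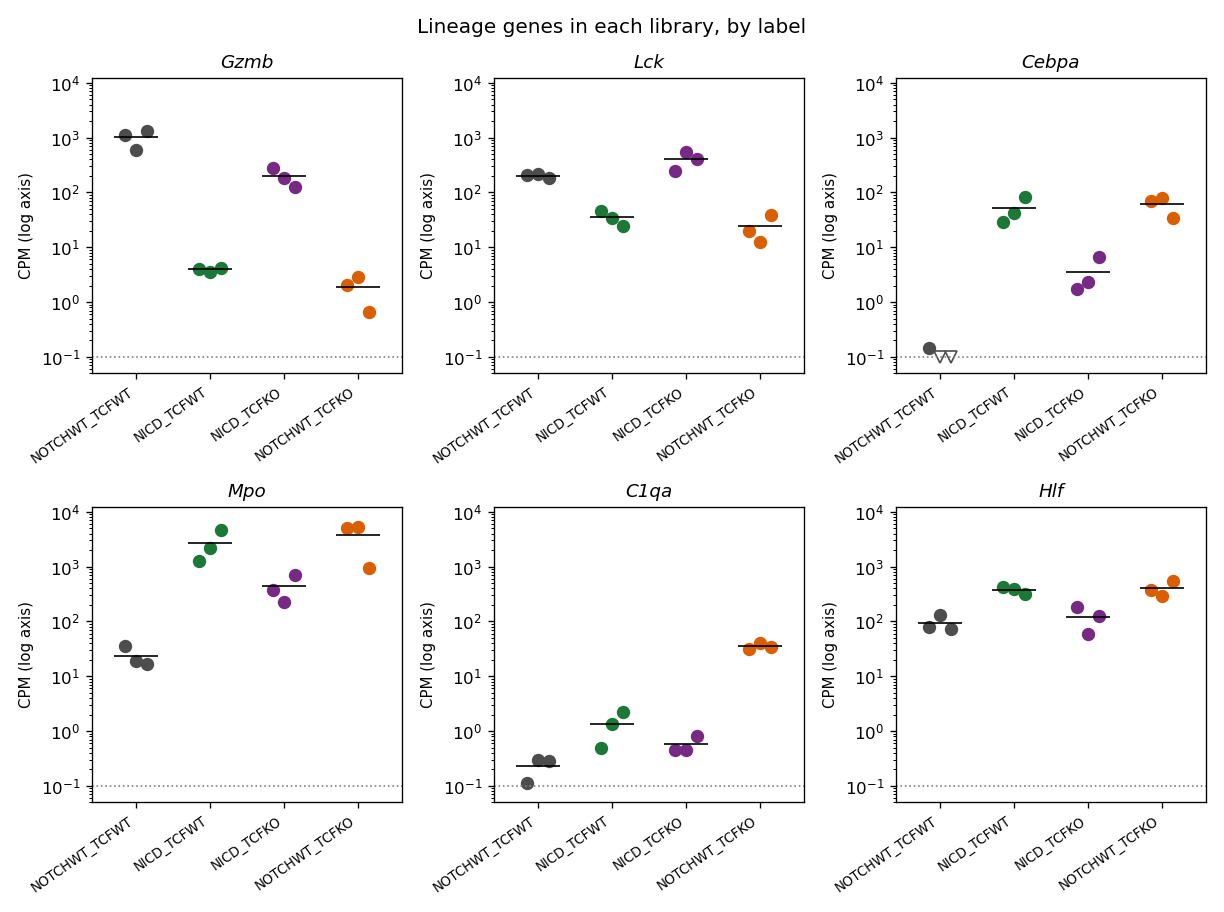
CPM of Gzmb, Lck, Cebpa, Mpo, C1qa and Hlf (log axis) in each of the 12 libraries, by labelled group; points are libraries, horizontal lines group means, the dotted line marks 3 counts in the shallowest library (0.099 CPM) and open triangles are libraries below it. C1qa is at 35.4 CPM in the libraries labelled NOTCHWT_TCFKO and at 0.231 to 1.37 CPM in the other groups.

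N1IC in cells without Tcf7 is asked by the libraries labelled NICD_TCFKO against those labelled NOTCHWT_TCFKO. In the libraries labelled NICD_TCFKO 10 of 17 Notch target genes and 18 of 26 T cell receptor genes were higher (1 lower in each). With an estimated correlation the first list passed camera (adjusted p = 0.00378) and the other did not (adjusted p = 0.144). Il2ra rose from 0.712 ± 0.993 to 802 ± 438 CPM, Trbc2 from 0.554 ± 0.808 to 173 ± 83.7 CPM and Dtx1 from 0.208 ± 0.189 to 121 ± 51.3 CPM. Tcf7, stated to be deleted in both groups, differed between them by 8.89 ± 0.80 (adjusted p = 0.000141). Lower were Mrc1, the mannose receptor of macrophages, from 68 ± 11.8 to 0.429 ± 0.26 CPM, Siglec1 from 25.9 ± 4.78 to 0.0664 CPM, and C1qa from 35.4 ± 4.73 to 0.569 ± 0.197 CPM.

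Ptcra was at least 86-fold higher and Bcl11b higher by 7.56 ± 1.27. Prss2 was 4900-fold higher (counting interval 880 to 194000). Of the genes with no count in the libraries labelled NOTCHWT_TCFKO, those labelled NICD_TCFKO held Klk1b22 at least 171-fold, Itln1 at least 103-fold and the transporter Slc5a9 at least 74.6-fold higher. Lower genes were further Cd5l (3250-fold, counting interval 583 to 128000), Fcna (1660-fold, 567 to 8050) and Vcam1 (149 ± 35.5 to 1.23 ± 0.828 CPM). The lower genes also held the phagocytic receptor Mertk (-6.03 ± 0.45), the potassium channel Kcnj10 (14.2 ± 2.27 to 0.124 CPM) and Eps8l1 (25.5 ± 1.43 to 0.369 ± 0.23 CPM).

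T cell receptor genes rose in 18 and fell in 1 of 26 (22 and 1 adjusted over the list alone). Cd5 changed by 4.50 ± 0.45 and Thy1 by 3.90 ± 0.38, the lower one being Cd4 (-1.22 ± 0.25; camera adjusted p = 8.28e-19, and adjusted p = 0.144 with an estimated correlation). Cd3e was at 0.583 and 19.5 ± 13.6 CPM and did not pass (adjusted p = 0.0549), but passed without NOTCHWT_TCFKO 2 (adjusted p = 0.00664). Notch target genes rose in 10 and fell in 1 of 17 (11 and 3 adjusted over the list alone). Nrarp changed by 3.71 ± 0.16, Notch3 by 5.80 ± 0.45 and Hes1 by 4.37 ± 0.79 (list adjusted p = 3.06e-12, and adjusted p = 0.00378 with an estimated correlation). Their median log2 change was 3.71 and stays so with Ptcra at its bound, at least 86-fold. Further counts are followed in parentheses by those adjusted over the list alone. Early T lineage regulators rose in 12 and fell in 1 of 25 (12 and 2). Gata3 changed by 2.29 ± 0.28 and Ets1 by 1.54 ± 0.26 (list adjusted p = 6.79e-05, and adjusted p = 0.358 with an estimated correlation). Interferon-stimulated genes rose in 9 and fell in 1 of 29 (10 and 1). Xaf1 changed by 1.63 ± 0.17 and Rsad2 by -1.21 ± 0.26 (list adjusted p = 0.00401, and adjusted p = 0.587 with an estimated correlation). Dendritic cell and MHC class II genes rose in 6 of 16 (6), with Itgax at 3.90 ± 0.35. Of this list 0 fell in edgeR, DESeq2 or voom or at an unadjusted p under 0.05 (adjusted p = 0.0011, and adjusted p = 0.587 with an estimated correlation). Chromatin regulators rose in 7 and fell in 1 of 30 (8 and 1). Tle3 changed by 1.01 ± 0.15, Arid1a by 0.54 ± 0.08 and Dnmt3a by 0.58 ± 0.11 (list adjusted p = 0.0295, and adjusted p = 0.587 with an estimated correlation).

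Granulocyte and monocyte genes fell in 9 of 25 (12) and rose in 0 in edgeR, DESeq2 or voom or at an unadjusted p under 0.05, against libraries in which Fcna and C1qa were high. Cebpa changed by -4.11 ± 0.65, Csf3r by -1.83 ± 0.38 and Cd68 by -1.05 ± 0.19 (list adjusted p = 5.53e-05, and adjusted p = 0.587 with an estimated correlation). Megakaryocyte genes fell in 6 of 18 (8) and rose in 0 in edgeR, with 1 higher at an unadjusted p under 0.05, 1 in DESeq2 and 0 in voom. Pf4 changed by -3.03 ± 0.65, a call lost when only the 2 groups compared were fitted (adjusted p = 0.0676; list adjusted p = 0.000177, and adjusted p = 0.496 with an estimated correlation). Stromal and endothelial genes fell in 4 and rose in 1 of 11 (7 and 2), Vcam1 among them (adjusted p = 0.00304, and adjusted p = 0.473 with an estimated correlation). Stem cell genes fell in 5 and rose in 3 of 30 (5 and 3). Cdkn1c changed by -2.24 ± 0.42 and Ly6a by 1.44 ± 0.25 (list adjusted p = 0.0391, and adjusted p = 0.696 with an estimated correlation). Plasma cell genes fell in 1 of 11 (1), Sdc1 by -2.34 ± 0.48 (adjusted p = 0.0448, and adjusted p = 0.65 with an estimated correlation). Erythroid genes passed camera as lower (adjusted p = 0.000946, and adjusted p = 0.587 with an estimated correlation), with 1 of 20 lower (0). This was the carbonic anhydrase Car2 at -1.50 ± 0.37, whose call was lost without NICD_TCFKO 3 (adjusted p = 0.0632) or NOTCHWT_TCFKO 2 (adjusted p = 0.0734) and with only the 2 groups fitted (adjusted p = 0.0981). The other lists did not pass camera: lymphoid-primed progenitor genes rose in 7 and fell in 4 of 18 (7 and 4) and T-ALL oncogenes rose in 3 and fell in 4 of 18 (3 and 6). NK and innate lymphoid genes rose in 4 and fell in 2 of 18 (4 and 2) and cell cycle genes rose in 3 and fell in 1 of 30 (2 and 1). Among 16 p53 targets 0 passed in edgeR, with 4 higher at an unadjusted p under 0.05 and 1 higher each in DESeq2 and voom.

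In total 1650 genes were higher and 1292 lower of 16024 (18.4%), 700 and 603 at least 2-fold, and 1330 and 1010 with the replicate block. Fitting only these 2 groups left 724 and 514. The counts moved by over 1.5 times without NICD_TCFKO 2 (1009 and 649) or 3 (1095 and 771) or NOTCHWT_TCFKO 1 (861 and 749), the lower count also without NOTCHWT_TCFKO 2 (786) and in DESeq2 (1998).

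Whether the effect of labelled Tcf7 loss differs with labelled N1IC was tested by the interaction, positive where the change on labelled Tcf7 loss is higher with labelled N1IC than without. Among the positive terms were 18.56 ± 0.78 for Dtx1, 16.68 ± 1.19 for Trbc2, 14.72 ± 0.81 for Gzmb and 9.65 ± 1.15 for Hes1, which rose with labelled Tcf7 loss in one background and fell in the other. Il2ra had a term of 13.07 ± 1.37, with a rise in the libraries labelled N1IC and no call without (-1.48 ± 0.92, adjusted p = 0.292). Tcf7 (10.32) and Notch1 (4.04 ± 0.32) were themselves positive. Negative terms were found for the myeloid regulator Cebpa (-13.65 ± 1.16), Slc16a11 (-14.02), Flt3 (-5.22 ± 0.43), Cdkn1c (-5.83 ± 0.61) and Bcl2 (-3.64 ± 0.26). Bcl11b had 7.26, a call lost without NOTCHWT_TCFWT 3 (adjusted p = 0.0613) and in voom (adjusted p = 0.156).

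By list, interaction terms were positive for 9 and negative for 4 of 17 Notch target genes (11 and 4 adjusted over the list alone; camera adjusted p = 2.3e-12, and adjusted p = 0.00231 with an estimated correlation). Values in parentheses below are adjusted over the list alone. T cell receptor genes were positive in 15 and negative in 2 of 26 (15 and 2). Fyn had a term of 2.26 ± 0.20 and Cd5 of 5.98 ± 0.60 (list adjusted p = 2.44e-12, and adjusted p = 0.332 with an estimated correlation). Of 25 granulocyte and monocyte genes 17 were negative (18) and 0 positive in edgeR, DESeq2 or voom or at an unadjusted p under 0.05. Mpo had a term of -9.97 ± 1.20 and Csf3r of -4.27 ± 0.54 (list adjusted p = 1.68e-08, and adjusted p = 0.332 with an estimated correlation). Early T lineage regulators were positive in 12 and negative in 3 of 25 (13 and 3). Ikzf2 had a term of 1.91 ± 0.12 and Gata3 of 2.67 ± 0.39 (list adjusted p = 0.00102, and adjusted p = 0.332 with an estimated correlation). Stem cell genes were negative in 13 and positive in 3 of 30 (13 and 3), with Hlf at -3.75 ± 0.57 and Mycn at 4.44 ± 0.31 (adjusted p = 0.00546, and adjusted p = 0.69 with an estimated correlation). Megakaryocyte genes were negative in 10 and positive in 1 of 18 (13 and 1), with Pf4 at -8.06 ± 0.97 (adjusted p = 0.00015, and adjusted p = 0.332 with an estimated correlation). Interferon-stimulated genes were positive in 15 and negative in 1 of 29 (16 and 2; adjusted p = 0.00102, and adjusted p = 0.528 with an estimated correlation). Chromatin regulators were positive in 13 of 30 (14) and negative in 0 in edgeR, DESeq2 or voom or at an unadjusted p under 0.05. Arid1a had a term of 0.88 ± 0.11 and Ezh2 of 0.67 ± 0.13 (list adjusted p = 0.00253, and adjusted p = 0.332 with an estimated correlation). Dendritic cell and MHC class II genes were positive in 7 and negative in 1 of 16 (7 and 1; adjusted p = 0.00546, and adjusted p = 0.528 with an estimated correlation). Stromal and endothelial genes were negative in 5 and positive in 1 of 11 (5 and 1; adjusted p = 0.00151, and adjusted p = 0.332 with an estimated correlation). Of the other lists, none of which passed camera, p53 targets were positive in 8 of 16 (8), with Trp53inp1 at 1.97 ± 0.31, and 0 negative in edgeR, DESeq2 and voom, with 1 lower at an unadjusted p under 0.05.

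The interaction term passed for 4389 genes of 16024 (27.4%), 2219 positive and 2170 negative, 1983 and 1971 with the replicate block. Across the 5 contrasts, 49 of the 115 tests of a list passed camera with the preset correlation and 5, all of Notch target genes, with an estimated one.

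Genes higher in the libraries labelled NICD_TCFWT than in those labelled NOTCHWT_TCFWT and lower in those labelled NICD_TCFKO than in those labelled NICD_TCFWT numbered 556, Cebpa, Tpsb2 and Pf4 among them; 690 genes, with Dtx1, Hes1 and Trbc2, had both signs turned. Independent lists of these sizes would share 87.6 and 113. Both contrasts use the libraries labelled NICD_TCFWT with opposite sign, so part of each excess may come from this sharing; simulated unchanged groups against those libraries gave at most 0 and 1 such genes in 20 simulations. At an unadjusted p under 0.05 the simulations gave a mean of 59.8 and 91 against 1334 and 1430 observed. No group changed in these simulations and a mean of 0.05 genes was called per contrast, so almost no overlap of called genes could arise. How much the sharing adds where groups do differ was not simulated. With the replicate block the overlaps were 433 and 562. They moved by over 1.5 times without NICD_TCFWT 1 (279 and 354), 2 (249 and 381) or 3 (303 and 403) or NICD_TCFKO 2 (293 and 441), the first also without NICD_TCFKO 3 (311) and in DESeq2 (920).

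The 2 contrasts of labelled N1IC share no library. They had 128 genes higher in both, Zfp990 among them, and 41 lower in both, where independent lists would share 175 and 126; with the replicate block these were 103 and 34. In opposite directions 515 genes were higher with Tcf7 labelled intact and lower with it labelled deleted, and 602 the reverse, against 137 and 161 for independent lists. Of the genes changed on labelled Tcf7 loss, 29 were higher and 7 lower in both backgrounds, against 126 and 86.2, and 513 and 425 turned direction, against 121 and 89.5. The count higher in both N1IC contrasts was 79 without NOTCHWT_TCFKO 1. The count lower in both was 82 in DESeq2, 23 without NOTCHWT_TCFWT 1, 23 and 25 without NICD_TCFWT 1 and 2, 27 without NICD_TCFKO 3, and 21, 23 and 78 without NOTCHWT_TCFKO 1, 2 and 3.

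Since Notch1 and Dtx1 split the groups into pairs, 2 further contrasts were chosen after seeing the data. Libraries labelled NICD_TCFKO, against those labelled NOTCHWT_TCFWT, had 642 genes higher and 368 lower of 16024 (6.3%). Il2ra rose from 1.9 ± 1.29 to 802 ± 438 CPM, Tcrg-C2 from 0.0926 to 118 ± 74.4 CPM and St6galnac2, a sialyltransferase, from 0.0582 to 63.6 ± 30.9 CPM. The kinase Frk fell from 24.2 ± 3.92 to 3.06 ± 2.31 CPM and the receptor Adgrg6 from 26 ± 9.47 to 1.68 ± 1.73 CPM. T cell receptor genes rose in 13 of 26 (20 adjusted over the list alone; adjusted p = 2.19e-13, and adjusted p = 0.247 with an estimated correlation). Notch target genes rose in 3 and fell in 1 of 17 (5 and 4 adjusted over the list alone; camera adjusted p = 0.281).

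Libraries labelled NOTCHWT_TCFKO, against those labelled NICD_TCFWT, had 214 genes higher and 246 lower (2.87%), the smallest numbers of the 6 pairwise contrasts. Among the largest increases were Fcna from 0.771 ± 0.487 to 41.1 ± 7.49 CPM, Mrc1 from 1.56 ± 1.04 to 68 ± 11.8 CPM and C1qa from 1.37 ± 0.892 to 35.4 ± 4.73 CPM. Zfp990 fell from 98.3 ± 6.04 to 0.386 ± 0.236 CPM, Tpsb2 from 26 ± 6.44 to 0.496 ± 0.377 CPM and the phosphodiesterase Gdpd3 from 46.2 ± 22.1 to 1.81 ± 0.182 CPM. Interferon-stimulated genes fell in 2 of 29 (7 adjusted over the list alone; adjusted p = 0.00237, and adjusted p = 0.762 with an estimated correlation).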

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

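The tests of mature T cells, of Tcf7 and of the median of the Notch target list were chosen only after the result was seen. Those of Gt(ROSA)26Sor, of macrophage genes and of the share of the top 10 genes were chosen after the patterns they address had been seen. Their own values had not been seen then, except those of C1qa and Mertk. The rule for macrophage genes required calls of C1qa, already seen, and of C1qb and C1qc. The tests of other splits were chosen before their counts were seen.

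The interaction test marked every result of this part: it called 2219 genes with a positive and 2170 with a negative term, so that the effect of labelled Tcf7 loss differed with labelled N1IC. Positive log2 terms were 18.56 for Dtx1, 16.68 for Trbc2, 16.38 for Prss2, 14.72 for Gzmb, 14.66 for ENSMUSG00000096312, 13.07 for Il2ra, 10.32 for Tcf7, 9.65 for Hes1, 9.31 for Notch3, 7.93 for Nrarp, 4.04 for Notch1 and 2.67 for Gata3. Bcl11b had 7.26, a call lost without NOTCHWT_TCFWT 3 (adjusted p = 0.0613). Negative terms were -18.28 for Tpsb2, -17.07 for Cd5l, -16.48 for Fcna, -14.02 for Slc16a11, -13.65 for Cebpa and -0.94 for Myc. These are 19 of the 82 called genes named for the interaction, and the other 63 are included in its counts. Groups of 3 libraries were not searched for outlying libraries.

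Dtx1, Hes1, Gzmb and Trbc2 were high in the libraries labelled NOTCHWT_TCFWT and NICD_TCFKO and low in those labelled NICD_TCFWT and NOTCHWT_TCFKO, whereas Il2ra, Bcl11b and Cd3g were high in those labelled NICD_TCFKO alone and at 1.9, 0.379 and 0.0582 CPM in those labelled NOTCHWT_TCFWT. Correct labels with a lowering of Notch target genes by N1IC are argued against by the median of the Notch target list, 3.71 in the libraries labelled NICD_TCFKO against those labelled NOTCHWT_TCFKO, and by Tcf7, higher by 5.34 (SE 0.66, adjusted p = 0.00276) in those labelled NICD_TCFKO than in those labelled NOTCHWT_TCFWT, although remaining exons would still be counted. RNA from mature alpha-beta T cells in the libraries labelled NICD_TCFKO is argued against by Trac, with 0, 2 and 1 counts there, 7.17e-05 of those of Trbc1 and Trbc2, against 30 counts and 0.341 in NOTCHWT_TCFKO 2. RNA from gamma-delta T cells, which lack Trac, stays open with Tcrg-C1 at 160 and Tcrg-C2 at 118 CPM, as does RNA from immature T cells: Trac, Cd3d, Cd3e and Cd3g added up to 0.15 of the level of Tcf7, and to 0.822 with Lck, a gene also at 203 ± 18.2 CPM in the libraries labelled NOTCHWT_TCFWT, but the first sum, although under its lower bound, rests on an assumed profile of a T cell and the other lay between its bounds, and the Lin- gate would remove cells that carry T cell lineage markers. Labels exchanged among the groups NOTCHWT_TCFWT, NICD_TCFWT and NICD_TCFKO are a candidate explanation that stays open: Gt(ROSA)26Sor, the gene at the R26 locus, was below the other 6 libraries in 3 of the 6 with high Dtx1 where all 6 were predicted, and changed by 0.195 (SE 0.113) with labelled N1IC where correct labels predicted a fall, so by the rules set before it counted against both readings, but it was set aside for both after it was seen because it also differed 5.31-fold between NOTCHWT_TCFKO and NOTCHWT_TCFWT and 2.5-fold between NOTCHWT_TCFKO and NICD_TCFWT, more than the loss of 1 of 2 alleles gives; other measures run as the labels say, with 550 genes higher and 394 lower along labelled N1IC, Zfp990 among them (98.3 and 82.8 against 0.368 and 0.386 CPM). Strain or the eGFP gate could set the same groups apart, so these measures do not decide. The second names do not decide either, since their meaning was not settled. CTRL and Tg could follow the labels or stand for libraries without and with a transgene. The latter would go against the label N1IC of those named CTRL. A response to N1IC that turns direction with Tcf7, the biological difference that the design names, stays open too. Such a response was not tested apart from the interaction itself.

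Cd5l and Fcna belong to a group of genes high in the libraries labelled NOTCHWT_TCFKO. Of a list of 18 macrophage genes 16 were measured and 13 were higher than in the libraries labelled NOTCHWT_TCFWT, with a median log2 change of 3.24 (2.99 over the 14 without C1qa and Mertk, which had been seen before), and C1qb reached 30.2, C1qc 33.6, Hmox1 59.4 and Apoe 156 CPM; 2 of the 16 also stand in the fixed lists, and LSK cells labelled NOTCHWT_TCFWT already held Apoe at 13.5 and Ctsb at 113 CPM. A few genes taking most of the counts is argued against by the share of the top 10 genes, which was 1.03 times that in the libraries labelled NOTCHWT_TCFWT. These values are consistent with RNA from macrophages in the libraries labelled NOTCHWT_TCFKO, although Csf1r (72.2 ± 41.6 against 67.6 ± 25.6 CPM), Slc40a1 (110 ± 32 against 14.9 ± 16.2 CPM, adjusted p = 0.073) and Lgmn (22.5 ± 4.76 against 13.2 ± 4.47 CPM, adjusted p = 0.0798) did not pass and the Lin- gate would remove macrophages that carry lineage markers. An effect of Tcf7 loss on these genes within LSK cells, which the design names, stays open and untested.

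Among 100 splits of the 12 libraries, the real one included, only the real one called as many interaction genes (4389, the highest other 889). This share lay under the bound of 0.05. The other splits mix libraries of different labelled groups, which widens the spread within each group. The rank of the real split therefore speaks only against an arbitrary grouping of these libraries, and not against other traits that differ between the groups. For the pairwise contrasts the 10 splits of 6 libraries are too few for a share under 0.05. The real split and the highest other gave 3263 and 1 genes for labelled NICD_TCFWT against NOTCHWT_TCFWT, 1986 and 4 for NICD_TCFKO against NICD_TCFWT, 3413 and 0 for NOTCHWT_TCFKO against NOTCHWT_TCFWT, 2942 and 2 for NICD_TCFKO against NOTCHWT_TCFKO, 1010 and 1 for NICD_TCFKO against NOTCHWT_TCFWT, and 460 and 10 for NOTCHWT_TCFKO against NICD_TCFWT.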

How the results depend on the processing

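The covariate for sex was chosen only after the results were seen; the other alternatives of this part were chosen before. No named gene that passed in either setting and no list that passed in both reversed its direction under any alternative run; genes and lists that passed in neither could turn, as NK and innate lymphoid genes did in NOTCHWT_TCFKO against NOTCHWT_TCFWT (camera lower, adjusted p = 0.999; fry higher, adjusted p = 0.985). Of 262 counts under alternatives, 214 stayed within 1.5 times the reported value and 48 did not, 42 of these on leaving out 1 library. DESeq2 called 1468 genes lower in NICD_TCFKO against NICD_TCFWT (825 reported), 1998 lower in NICD_TCFKO against NOTCHWT_TCFKO (1292), 920 higher with labelled N1IC and lower on labelled Tcf7 loss (556) and 82 lower in both N1IC contrasts (41). Fitting only the groups compared gave 724 higher and 514 lower in NICD_TCFKO against NOTCHWT_TCFKO (1650 and 1292). The cause was not tested for either setting. Leaving out 1 library in turn, which leaves fewer samples, gave from 1073 (without NOTCHWT_TCFWT 3) to 1411 higher and 873 (without NICD_TCFWT 1) to 1143 lower in NICD_TCFWT against NOTCHWT_TCFWT, 564 (without NICD_TCFWT 1) to 1463 higher and 332 (without NICD_TCFWT 2) to 1225 lower in NICD_TCFKO against NICD_TCFWT, 1118 (without NOTCHWT_TCFWT 1) to 1993 higher and 1008 (without NOTCHWT_TCFKO 1) to 1854 lower in NOTCHWT_TCFKO against NOTCHWT_TCFWT, and 861 (without NOTCHWT_TCFKO 1) to 1786 higher and 649 (without NICD_TCFKO 2) to 1516 lower in NICD_TCFKO against NOTCHWT_TCFKO. The overlaps ranged from 249 (without NICD_TCFWT 2) to 689 for higher with N1IC and lower on Tcf7 loss, 354 (without NICD_TCFWT 1) to 734 for the reverse, 79 to 156 for higher in both N1IC contrasts and 21 to 78 for lower in both (lowest without NOTCHWT_TCFKO 1, highest without NOTCHWT_TCFKO 3), and the interaction from 1703 to 2244 positive and 1774 to 2436 negative. With the covariate for sex the counts were 1383 and 1192, 1058 and 834, 1870 and 1812, 1824 and 1658, and for the interaction 1922 and 1969. In NICD_TCFWT against NOTCHWT_TCFWT, 1156 of the 1701 higher and 996 of the 1562 lower genes stayed called with it. For named genes 8946 comparisons kept their side of the threshold, 507 lost the call (342 on leaving out 1 library) and 164 gained it; 104 of the 415 called genes lost their call under at least 1 setting. For lists 496 kept their side, 60 lost the call (44 with an estimated correlation) and 19 gained it. Taken over all groups, the replicate numbers did not pair the samples: 6 of 18 same-number correlations exceeded 0.1 (-0.405 to 0.458), and 3 of 12 libraries matched best with their own number. Between NICD_TCFWT and NICD_TCFKO they were 0.312, 0.0976 and 0.458, against -0.446 to 0.258 for different numbers, so a pairing there stays open. Replicate 3 of NOTCHWT_TCFWT, NICD_TCFWT and NICD_TCFKO, set as 1 library sheet, correlated at 0.156 to 0.458. These libraries correlated at 0.212, 0.463 and 0.471 with NOTCHWT_TCFKO 2, outside that sheet, so the correlation was not particular to it. With the covariate for library sheets NICD_TCFKO against NICD_TCFWT gave 1055 higher and 752 lower. Contrasts that share the libraries labelled NICD_TCFWT had a covariance of -0.151 when simulated without any change, against -0.81 observed (correlation -0.499 and -0.569). The 3 control libraries are too few to be split between them. Depth limits genes below 0.099 CPM, the level of 3 counts in the shallowest library.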

Other observations

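The test of a strain variant and the main effects of labelled N1IC and labelled Tcf7 loss were chosen only after the results were seen; the tests of genes near Tcf7 and near 3 other loci use these main effects, and were chosen before their own values were seen but after the groups had been compared. Mast cell and basophil genes took different courses over the labelled groups. Cpa3 was at 276 ± 64.5 and 206 ± 49.6 CPM in the libraries labelled NOTCHWT_TCFWT and NICD_TCFKO, and at 61.5 ± 1.57 and 56 ± 17.3 CPM in those labelled NICD_TCFWT and NOTCHWT_TCFKO (interaction 4.05 ± 0.36, adjusted p = 3.84e-05). Il4, a cytokine of basophils and T cells, was at 12.1 ± 1.52 CPM in the libraries labelled NOTCHWT_TCFWT and at 1.13 ± 0.584, 1.84 ± 1.53 and 0.636 ± 0.438 CPM in those labelled NICD_TCFWT, NICD_TCFKO and NOTCHWT_TCFKO. The mast cell protease Mcpt1 was at 59.1 ± 96.2 CPM in the libraries labelled NOTCHWT_TCFWT; its change of -9.32 in NICD_TCFWT against NOTCHWT_TCFWT was -5.27 without NOTCHWT_TCFWT 3 (adjusted p = 0.0704), and the call was also lost without NICD_TCFWT 1 (adjusted p = 0.116), 2 or 3 (adjusted p = 0.113 each).

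Among Wnt target genes Apcdd1, a membrane inhibitor of Wnt signalling, was at 4.5 ± 0.598 and 6.11 ± 0.455 CPM in the libraries labelled NOTCHWT_TCFWT and NICD_TCFKO, and at 16.1 ± 3.95 and 9.77 ± 3.06 CPM in those labelled NICD_TCFWT and NOTCHWT_TCFKO (interaction -2.51 ± 0.35, adjusted p = 0.000527). Tcf7l1, a relative of Tcf7, had an interaction term of -3.31 ± 0.61 (adjusted p = 0.00262). Lef1, the closest relative of Tcf7, was at 3.66 CPM in the libraries labelled NICD_TCFKO, with 0.45, 3.34 and 7.2 CPM in the 3 libraries, and at most 1.41 CPM in any other library; it did not pass in any of the 4 pairwise contrasts.

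Some genes followed the N1IC label, and with it the eGFP gate, where Dtx1 did not. Zfp990 was at 98.3 ± 6.04 and 82.8 ± 21.9 CPM in the libraries labelled NICD_TCFWT and NICD_TCFKO and at 0.368 ± 0.233 and 0.386 ± 0.236 CPM in those labelled NOTCHWT_TCFWT and NOTCHWT_TCFKO. Rps13-ps1 was at 85.5 ± 12.4 and 79.5 ± 20.3 against 0.924 and 0.882 CPM in the same order, and BC018473 at 36.8 ± 19.5 and 117 ± 21.4 against 0.06 and 0 CPM; these genes were chosen after their values were seen. The main effect of labelled N1IC called 550 genes higher and 394 lower, and that of labelled Tcf7 loss 352 and 217. A main effect averages 2 contrasts, so the counts for labelled N1IC also hold genes high in NICD_TCFKO alone, such as Bcl11b.

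Such genes, near 0 in whole groups, may mark strain segments of the mixed C57BL/6J and Sv/129 background. Of the 100 genes changed by over 3 on the log2 scale in the main effect of labelled N1IC, 30% had another such gene within 1 Mb, against a median of 14% in 1000 random draws (permutation p = 0.003). Among as many of the largest genes of the interaction the share was 37%. The 100 genes also held genes high in NICD_TCFKO alone, such as Bcl11b, and neighbouring T cell receptor genes such as Trbj1-1 and Trbj1-2. BC018473, named above, lay on chromosome 11 within 1 Mb of Cygb, St6galnac2 and Mxra7 of this set. Zfp990 lay on chromosome 4 within 1 Mb of Zfp986 and Gm13230, while Rps13-ps1 on chromosome 8 had no such neighbour. Neighbouring genes of 1 family were not removed from either set. The 2 shares therefore cannot tell strain segments from such clusters, and the test leaves a strain variant open. The eGFP gate and an effect of N1IC itself, which the design names, coincide with these groups and stay open as untested.

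A lox-flanked Tcf7 allele could bring linked sequence that sets groups apart near Tcf7. Within 10 Mb of Tcf7, genes were called in the main effect of labelled N1IC with an odds ratio of 1.14 (95% interval 0.623 to 1.93, Fisher's exact p = 0.57, 15 of 226 genes) and in that of labelled Tcf7 loss with 0.24 (0.0288 to 0.881, exact p = 0.0272, 2 of 226 genes), so neither held an excess. The second value met the bound set before it was seen against an allele in the libraries labelled Tcf7-deleted; that bound was set aside after it was seen, because the labels do not give the strain of the sequence around the lox sites, and without a strain difference no excess would follow. The 24 such tests over 4 loci, 5 and 10 Mb and 3 splits gave 6 at an unadjusted p under 0.05 and 3 at an adjusted p under 0.05. Of these 3, genes near Notch1 were called less often in the main effect of labelled N1IC (odds ratio 0.184 within 5 Mb, adjusted p = 0.0379, and 0.356 within 10 Mb, adjusted p = 0.0475) and genes within 10 Mb of Mx1 more often in the interaction (31 of 68, odds ratio 2.23, adjusted p = 0.0355).

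Gt(ROSA)26Sor was at 2.42 ± 0.359, 5.16 ± 0.207, 7.93 ± 0.983 and 12.9 ± 1.02 CPM in the libraries labelled NOTCHWT_TCFWT, NICD_TCFWT, NICD_TCFKO and NOTCHWT_TCFKO, and so differed between every pair of labelled groups without overlap.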
